A study of Mus musculus with 4 samples.

How the data were processed

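RNA was measured in cells sorted from mouse colonic epithelium, in 2 libraries of Reg4+ DCS cells and 2 of Lgr5+ cells. Per the labels' protocols, cells were sorted into Trizol, total RNA was prepared as CEL-seq libraries, and these were sequenced as 50 bp paired-end reads on a HiSeq 2500. The submitters' processing notes name BWA 0.6.2-r126 and the genome build mm10. The step from alignments to genes, the annotation, the use of molecular identifiers and any filter are not given in the sources used here. CEL-seq tags the 3′ ends of transcripts, so that a gene's value does not scale with its length, and values without molecular identifiers would include copies made by amplification. The design text states that sorting and library preparation were done in 2 rounds as biological replicates. The p-values rest on the spread within each pair of libraries, pooled over both populations and drawn toward the spread of other genes. The design text does not say whether the replicate number of a Reg4+ DCS library and of an Lgr5+ library marks a shared round.

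The authors deposited 1 table of RPM (reads of a gene scaled to a fixed total) for 14519 genes in 4 columns, each of which sums to 1000000. An RPM value is relative to all reads in the column, so that abundant transcripts lower the values of the others. In both Lgr5+ columns 100% of values were whole multiples of the worth of 1 read within 0.01 reads, which gave 5205723 and 7955340 reads. Values in the Reg4+ DCS columns were sums of multiples of 2 step sizes, as the mean of 2 separately scaled parts gives. They were decoded uniquely for 99.8% of genes in replicate 1 (5523304 and 1890960 reads) and 98.6% in replicate 2 (3004289 and 2443971 reads), leaving 22 and 203 genes ambiguous. What the 2 parts were is not given in the sources used here, and each column was counted as 1 replicate. The spread between the Reg4+ DCS columns is thus one of averages, unlike that of the Lgr5+ columns. A value of 1 read was worth 0.192 and 0.126 RPM in the Lgr5+ libraries and 0.181 to 0.529 RPM in the parts of the Reg4+ DCS libraries. The decoding was tested on 2 simulated columns, in which at least 99.6% of genes were decoded uniquely and 100% of those correctly. Among the deposited values, 12874 genes were above 0 in each Reg4+ DCS library and 14209 and 14211 in the Lgr5+ libraries. Genes that other cells use widely were among those at 0, and such genes are reported only as listed at 0, without a fold change. Some genes were at 0 in the same part of both Reg4+ DCS columns and above 0 in the other part. That 0 entered their means and folds.

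Symbols were used as the authors' table gives them. Of its 14519 entries, 13608 matched GENCODE M21 (GRCm38, the same assembly as mm10) by symbol and chromosome, and coordinates come from that annotation. There were 2 symbols listed on 2 chromosomes. Some symbols are older ones: Clca3 is the gene called Clca1 today, and the entry Clca1 is another gene. Of the members of 34 gene lists, 3 were matched through a synonym.

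Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend=TRUE) on log2(RPM + 1), for genes with an RPM of at least 5 in at least 2 libraries, with group as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are Reg4+ DCS minus Lgr5+ on the log2(RPM + 1) scale, which understates the change of low genes. Folds in the text are ratios of mean RPM. Of 139 named genes above 0 in every library, 45 had a fold more than 1.5 times away without 1 library. Gene lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with the adjustment made over 24 lists. An estimated correlation and the rotation test fry were run beside it. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries and not from the genes, so almost no list could pass. Camera compares a list with all other genes, while fry asks whether a list's genes move on balance one way. The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made after. The lists covered sort markers, epithelial identity, crypt base and reserve stem cells, Wnt targets and ligands, Notch ligands and receptors, EGF ligands, BMP and TGF-beta signalling, and secretory transcription factors. They also covered goblet, Paneth, enteroendocrine, tuft and absorptive cells, the Reg family, cell cycle phases and inhibitors, ribosomal proteins and ribosome biogenesis, oxidative phosphorylation, glycolysis, endoplasmic reticulum secretion, O-glycosylation, ephrins, cytokines, antigen presentation, leukocytes, stroma, erythrocytes, stress genes and mitochondrially encoded genes. Named genes were both sort markers, the 12 genes per direction with the largest absolute log2 fold change among those called, with the groups apart and a mean of at least 20 RPM in the higher group, and up to 4 members per list with the smallest p. Any member of the ligand, secretory factor and stem cell lists could be named as well. Some genes that this rule selects are not reported here. The other genes named were chosen after their values were seen: Muc2, Spink4, Lyz1, Mmp7, Reg3b, Reg3g, Cd24a, Tmed6, Galk1, Hspa8, Hspa1a, Hspa1b, Il4ra, Eno1, Rn45s, the entry Clca1, Xist, Ddx3x, 4 leukocyte genes and the Y-linked genes.

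Data were simulated with means and depths taken from the libraries and 200 changed genes (5 runs, dispersion 0.0526). The test recovered 21.0% of genes changed 2-fold and 95.8% of those changed 4-fold. On average 4.80 of 121.6 calls were false, and with no changed gene there were 0 calls by limma. A gene changed 2-fold could therefore often go uncalled. The simulation changed far fewer genes than the 3475 called in the deposited data, whose median log2 fold change was −0.47 on the RPM scale. The simulated rates of false calls therefore need not hold for the deposited data, nor for genes with a larger spread than that dispersion.

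The alternatives were pseudocounts of 0.5 and 5, no filter on low values or a minimum of 20 RPM, the replicate number as a block, and median-of-ratios, TMM and quantile scaling. RPM without ribosomal protein genes and the 10 highest genes, eBayes without a trend or with robust=TRUE, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, and leaving out each library in turn were also run. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other group. On the recovered reads edgeR called 2754 genes, 2092 of them also called by limma, and DESeq2 called 2717, of which limma called 1998. A fit and list tests on genes above 0 in every library and the list counts and folds without each library were added after the data were examined. Decoding, checks and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.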

Results

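The crypts of the mouse colon hold Lgr5+ stem cells at their base, and among them lie deep crypt secretory (DCS) cells, which make mucus and express Reg4. Both cell types were sorted from colonic epithelium by fluorescent reporters, Reg4-dsRed for DCS cells and Lgr5-GFP for stem cells, and their RNA was measured by CEL-seq, a method that reads the 3′ ends of barcoded and linearly amplified RNA. There were 4 libraries, 2 per population, and the design text describes the 2 rounds of sorting and library preparation as biological replicates. The comparison asks which genes define DCS cells against Lgr5+ cells and, since the series names DCS cells as a niche, which signals to stem cells they express. Expression was given for 14519 genes as RPM, the reads of a gene scaled to a fixed total per library. The read totals recovered from the RPM steps were 5205723 and 7955340 for Lgr5+ replicates 1 and 2. Each Reg4+ DCS column had the form of a mean of 2 separately scaled parts, of 5523304 and 1890960 reads for replicate 1 and 3004289 and 2443971 reads for replicate 2.

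Reg4+ DCS cells carried a goblet-type secretory program, with goblet cell genes, O-glycosylation enzymes and endoplasmic reticulum genes higher as lists than in Lgr5+ cells; stem cell, Wnt target and cell division lists were higher in Lgr5+ cells, as were the tuft cell genes above 0 in every library. These list calls used camera's preset correlation. With a correlation estimated from the 4 libraries 0 lists passed (adjusted p from 0.177 to 0.434 for those named here, and 0.436 for the tuft genes above 0). That version takes its degrees of freedom from the libraries, so a list could hardly pass whatever its correlation. For G2/M genes camera's adjusted p went from 1.01e-13 to 0.177, though their estimated correlation (0.00642) lay below the preset 0.01. Of the lists called, secretory transcription factors also lay below it (−0.0640). The others lay above it, at 0.330 for goblet genes and up to 0.972 for tuft genes. Where the true correlation is above the preset, the adjusted p printed for camera is too small. The failure to pass still neither upholds nor overturns the calls. Zg16, a mucus lectin that binds Gram-positive bacteria, stood at 14724 ± 3410.4 RPM in Reg4+ DCS cells and 207 ± 211 RPM in Lgr5+ cells (mean ± SD, n = 2 per group, as for every such pair). The Lgr5+ libraries had 356 and 57.6 RPM, and the Zg16 fold of 71.1 ranged from 41.3 to 255.7 without 1 library. Of 10183 genes tested with limma, 3475 changed, 731 of them higher in Reg4+ DCS cells and 2744 higher in Lgr5+ cells. Among these, 207 were at least 4-fold higher in Reg4+ DCS cells and 612 in Lgr5+ cells. Both libraries of 1 group lay above both of the other for 72.3% of the tested genes (1640 genes higher in Reg4+ DCS and 5723 higher in Lgr5+ cells), where chance gives 33.3%. That 33.3% assumes no shift common to all genes. On the RPM scale the median log2 fold change was −0.47, so the excess is not shown to be particular to single genes. Spearman's correlation across genes was at least 0.942 within a population and at most 0.813 between them.

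The split between directions depended on the scaling. On the deposited RPM scale the median log2 fold change of all tested genes (Reg4+ DCS minus Lgr5+) was −0.47, and 79.0% of calls were higher in Lgr5+ cells. Median-of-ratios scaling moved that median to 0.02 and gave 1591 genes higher in Reg4+ DCS and 1297 higher in Lgr5+ cells, or 44.9% of calls. All 731 genes called higher in Reg4+ DCS cells, and 1297 of the 2744 called higher in Lgr5+ cells, held their call under this scaling, and 0 calls turned to the other direction. The scaling divides each library by 1 factor (0.767 and 0.921 for Reg4+ DCS, 1.23 and 1.16 for Lgr5+ replicates 1 and 2). It so shifts nearly all genes toward Reg4+ DCS cells by a like amount. Calls in that direction could hardly be lost, and that all 731 held is no separate support for them. The total fell to 1419 without Reg4+ DCS replicate 1, with 359 and 1060 genes in the 2 directions. It was 2132 without Lgr5+ replicate 2 (559 and 1573), 2637 without Reg4+ DCS replicate 2 (349 and 2288), and 2321 without Lgr5+ replicate 1 (706 and 1615).

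**Figure D1:**
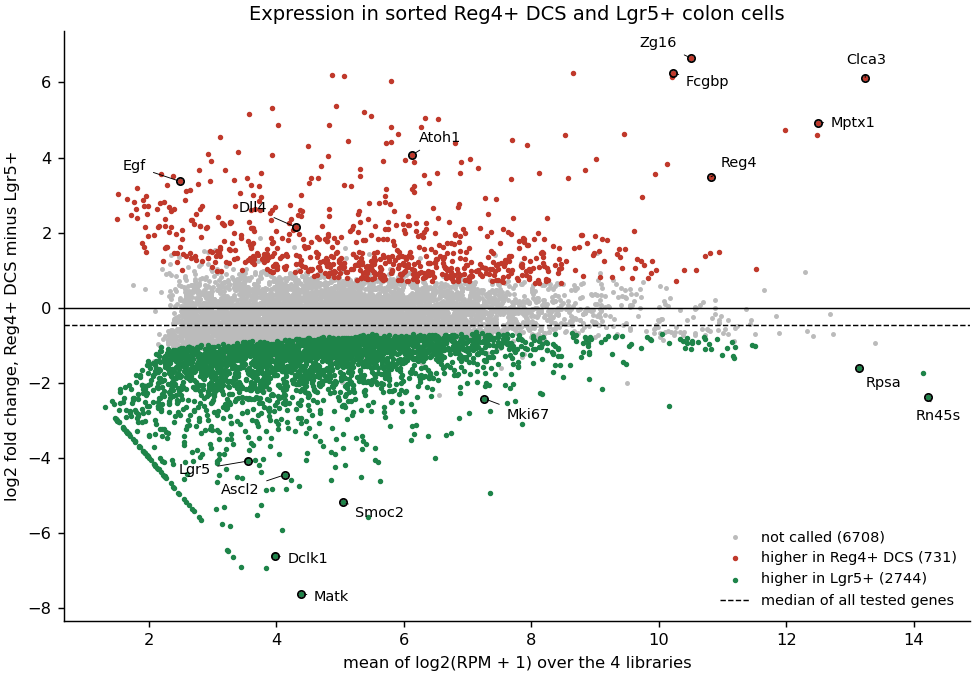
Each point is 1 of 10183 tested genes, with its mean log2(RPM + 1) over the 4 libraries on the x axis and its log2 fold change, Reg4+ DCS minus Lgr5+, on the y axis; red and green points passed the limma test in either direction and grey points did not. The dashed line marks the median of all genes at −0.47, and the straight lower left edge is formed by genes listed at 0 in both Reg4+ DCS libraries.

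The sort markers followed the labels. Reg4, a secreted lectin-like protein (mm10 chromosome 3, 98222156 to 98236748), stood at 6043 ± 204 RPM in Reg4+ DCS cells and 579.8 ± 306 RPM in Lgr5+ cells, 10.4-fold apart (7.59 to 16.6 without 1 library; log2 fold change 3.49, SE 0.37, adjusted p = 0.000554). Lgr5, the R-spondin receptor of stem cells (chromosome 10, 115450311 to 115587780), stood at 2.06 ± 1.52 and 47.6 ± 1.62 RPM, 23.1-fold higher in Lgr5+ cells (15.2 to 48.2 without 1 library; log2 fold change −4.08, SE 0.39, adjusted p = 0.000363). As both genes drove the sorting reporters, they check the labels and are no finding between the populations. Without either Lgr5+ library, Lgr5 and the other genes under 5 RPM in both Reg4+ DCS libraries missed the filter and were not tested. Reg4 was the single tested member of the Reg gene family list. Reg3b and Reg3g, bactericidal lectins, were listed at 0 in both Reg4+ DCS libraries and were below the filter, at 8.64 and 0.754 RPM (Reg3b) and 4.80 and 2.26 RPM (Reg3g) in the Lgr5+ libraries.

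Mucus and goblet cell genes rose together in Reg4+ DCS cells. Of 32 tested goblet genes, 29 were higher in Reg4+ DCS cells and 1 was higher in Lgr5+ cells, over all genes and adjusted over the list alone. The most abundant gene was Clca3, a mucus-processing protease that today bears the symbol Clca1, at 86623 ± 44523 RPM against 1552 ± 1472 RPM (55.8-fold, log2 fold change 6.13). Muc2, the gel-forming mucin of colonic mucus, was chosen after its values were seen and stood at 20881 ± 3924 against 810.5 ± 314 RPM (25.8-fold). Tff3, a trefoil peptide of the mucus, was 58.0-fold higher, and Fcgbp, a mucus protein that binds IgG, was 68.8-fold higher. Without any 1 library the folds ranged from 36.4 to 144 for Tff3, 47.1 to 128 for Fcgbp and 33.4 to 169 for Clca3, each lowest without Lgr5+ replicate 2 and highest without Lgr5+ replicate 1. Spink4, a secreted protease inhibitor also chosen after its values were seen, was 23.3-fold higher. Bcas1 and Sytl2, a granule-tethering protein, were 25.9-fold and 22.1-fold higher, and Klk1, a secreted kallikrein protease, 14.3-fold higher. The exception was the gene listed under the older symbol Clca1, which another gene bears today, at 0.619 and 0.742 RPM in the Reg4+ DCS and 21.1 and 25.8 RPM in the Lgr5+ libraries, and it was not tested without either Lgr5+ library. On the log2 scale the median of the list was 3.70, and limma's camera gave an adjusted p of 5.84e-33. It did not pass with an inter-gene correlation estimated from the 4 libraries (adjusted p = 0.254 with an estimated correlation), and neither did any other list. With so few libraries that version could hardly pass any list.

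Other genes with the largest rise in Reg4+ DCS cells included Sval1 (74.0-fold), Rep15, an effector of the trafficking GTPase Rab15 (83.4-fold), St6gal1, a sialyltransferase of glycoproteins (68.1-fold), and Best2, a bestrophin anion channel of goblet cells (66.8-fold). Capn9, a calpain protease of the digestive tract, was 61.2-fold higher, at 70.3 ± 3.50 against 1.15 ± 1.09 RPM. The annotated pseudogene 9030619P08Rik (75.4-fold) and the protein-coding Gm1123 (46.2-fold) were also in this group. These folds depended on the Lgr5+ libraries: without replicate 1 they were 349.8 for Rep15, 249 for 9030619P08Rik, 186 for Capn9, 140.1 for St6gal1 and 98.1 for Gm1123. Without replicate 2 those of Rep15, 9030619P08Rik, Capn9, St6gal1 and Gm1123 were 47.4, 44.4, 36.6, 45.0 and 30.2. Their log2 fold changes lay between 5.15 for Capn9 and 6.25 for Sval1, with SEs from 0.30 for Best2 to 0.59 for Rep15 and limma adjusted p from 0.000115 to 0.000341. The log2(RPM + 1) scale understates the change of genes with low values.

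Enzymes that build the sugar chains of mucins followed. Of 40 tested O-glycosylation genes, 26 were higher in Reg4+ DCS cells and 1 in Lgr5+ cells (27 and 2 adjusted over the list alone). Gcnt3, which makes the branched core structures of mucin glycans, was 14.5-fold higher (9.95 to 27.0 without 1 library), and A4gnt, which caps them with N-acetylglucosamine, was 14.3-fold higher (10.4 to 23.02). Galnt12, a starter enzyme of O-glycans, was 5.84-fold higher and Fut2, a fucosyltransferase, 5.55-fold higher. The member higher in Lgr5+ cells was Galk1, a galactokinase (1.69-fold, adjusted p = 0.0362), whose call was lost under median-of-ratios scaling (0.405) and without any 1 library (0.0562 without Reg4+ DCS replicate 2 to 0.161 without replicate 1). Over the list the median was 1.24 (camera adjusted p = 3.16e-20, and adjusted p = 0.177 with an estimated correlation).

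Genes of protein entry, folding and transport in the endoplasmic reticulum also rose as a group. Of 76 tested, 51 were higher in Reg4+ DCS cells and 1 was higher in Lgr5+ cells, or 61 and 2 adjusted over the list alone. Fkbp11, a peptidyl-prolyl isomerase of secretory cells, was 8.37-fold higher, Pdia5, a disulfide isomerase, 4.75-fold, and Tmed3, a cargo receptor, 4.29-fold. Herpud1, part of the machinery that removes misfolded proteins, stood at 329 ± 3.85 against 81.4 ± 4.85 RPM (4.04-fold). Tmed6, another cargo receptor, was the member higher in Lgr5+ cells (adjusted p = 0.0376), a call lost under median-of-ratios scaling (0.0971) and without Reg4+ DCS replicate 1 (0.209), and it was not tested without either Lgr5+ library. Over the list the median was 0.96 (camera adjusted p = 2.11e-34, and adjusted p = 0.177 with an estimated correlation). The count of higher members was 24 without Reg4+ DCS replicate 1 and 70 under median-of-ratios scaling.

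The Paneth cell list is of the granule-bearing antimicrobial cells of the small intestine. Of its 11 tested members, 8 were higher in Reg4+ DCS cells and 0 in Lgr5+ cells by limma (10 and 1 adjusted over the list alone, and 10 and 0 by edgeR). The 1 was Cd24a, a surface glycoprotein, also the 1 member in that direction at an unadjusted p under 0.05 (adjusted p over all genes = 0.0774, 0.0142 with the replicate number as a block, and 0.0259 without Lgr5+ replicate 2). With the block 10 members were higher in Reg4+ DCS and 1 in Lgr5+ cells. Mptx1, a mucosal pentraxin, was among the most abundant transcripts of Reg4+ DCS cells at 32157 ± 5983 RPM against 1109 ± 514 RPM (29.0-fold). Clps, the colipase that activates pancreatic lipase, was 43.4-fold higher. Pla2g2a, a phospholipase gene annotated as a polymorphic pseudogene, was 12.5-fold and Nupr1, a stress-induced nuclear protein, 12.4-fold higher. Lyz1, the Paneth cell lysozyme, stood at 1.62 and 0.908 RPM in the Reg4+ DCS libraries and 0.384 and 0.629 RPM in the Lgr5+ libraries, below the filter. Mmp7, the protease that activates defensins, was also below the filter. It was listed at 0 in both Reg4+ DCS libraries and at 0.192 and 0.126 RPM in the Lgr5+ libraries. These 2 genes were chosen after their values were seen. For the list the median was 3.60 (camera adjusted p = 1.14e-12, and adjusted p = 0.314 with an estimated correlation). Mptx1 has a close paralog, Mptx2, and how reads were split between such copies is not given in the sources used here.

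Transcription factors of the secretory lineage were higher in Reg4+ DCS cells for 10 of 13 tested, with 1 higher in Lgr5+ cells, and the counts adjusted over the list alone were also 10 and 1. Atoh1, the factor that commits intestinal progenitors to secretory fate, stood at 289 ± 54.7 against 16.1 ± 1.36 RPM (17.9-fold, log2 fold change 4.07, SE 0.25, adjusted p = 0.000143). Spdef, which drives goblet cell maturation, stood at 522 against 40.2 RPM (log2 fold change 3.73). Gfi1, a repressor downstream of Atoh1, was 14.3-fold (9.20 to 31.6 without 1 library) and Bhlha15, a regulator of secretory granules, 16.9-fold higher (11.5 to 28.7). Xbp1, the unfolded protein response factor, was 3.86-fold higher and Creb3l4, a membrane-bound factor of the endoplasmic reticulum, rose by 2.79 on the log2 scale. Klf4, a goblet cell differentiation factor, was 3.46-fold higher (2.43 to 6.01 without 1 library), but its adjusted p of 0.00795 became 0.0615 without Reg4+ DCS replicate 1 and 0.0556 without replicate 2. Sox4, a factor of progenitors and early tuft and endocrine cells, went the other way, at 9.18 ± 3.05 against 281 ± 194 RPM (log2 fold change −4.63). The median over the list was 1.93 (camera adjusted p = 2.26e-09, and adjusted p = 0.177 with an estimated correlation). The count of higher members was 5 without Reg4+ DCS replicate 1 and 6 without replicate 2.

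Signals to stem cells were examined by family. The Notch ligands Dll4 and Dll1, membrane proteins that activate Notch on neighbouring cells, were higher in Reg4+ DCS cells. Dll4 (chromosome 2, 119325784 to 119335962) stood at 41.2 ± 10.1 against 8.58 ± 2.54 RPM, 4.80-fold apart (log2 fold change 2.14, SE 0.33, adjusted p = 0.00244). Dll1 (chromosome 17, 15367354 to 15376872) stood at 48.6 ± 21.1 against 18.1 ± 5.44 RPM, 2.69-fold apart (log2 fold change 1.34, SE 0.37, adjusted p = 0.0254), and its call was lost without Reg4+ DCS replicate 2 (adjusted p = 0.121) and with no filter on low values (0.0556). Jag1, another ligand, did not pass, at 5.98 ± 0.745 against 11.4 ± 0.299 RPM (adjusted p = 0.0694), though it was among the calls adjusted over the list alone (2 higher and 1 lower of 3). By limma without a trend Jag1 was called higher in Lgr5+ cells (adjusted p = 0.0445). Dll3 and Jag2 lay below the filter.

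Of the EGF family ligands, Egf itself, a growth factor that stem cells need in culture, was higher in Reg4+ DCS cells. Egf (chromosome 3, 129677565 to 129755316) stood at 11.9 and 24.5 RPM in the Reg4+ DCS libraries and 0.768 and 0.754 RPM in the Lgr5+ libraries (log2 fold change 3.36, SE 0.41, adjusted p = 0.000942); without either Reg4+ DCS library it missed the filter and was not tested. It was the 1 call of 3 tested members, also adjusted over the list alone. Hbegf (−0.39, adjusted p = 0.226) and Areg (−0.30, adjusted p = 0.501), other ligands of the EGF receptor, did not pass. Of the Wnt ligands and their secretion factors, 3 were tested and 0 passed with limma, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05, while edgeR called 1, Porcn. Wnt4 had a log2 fold change of −0.81 (adjusted p = 0.162; 0.0451 without Reg4+ DCS replicate 2), and Wls, the carrier that exports Wnts, −0.64 (adjusted p = 0.122). Porcn, the enzyme that adds a lipid to Wnts, stood at 0.75 (adjusted p = 0.110), and was called higher in Reg4+ DCS cells under median-of-ratios scaling (adjusted p = 0.0207) and by edgeR (0.0271). Of the Wnt ligands on the list only Wnt4 was tested. Wnt5a, Wnt5b, Wnt6, Wnt8b, Wnt10b and Wnt11 lay below the filter, and the others, Wnt3 among them, had no values. R-spondins were not among the genes analysed here. These results therefore say little on Wnt signals from either population.

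On the receiving side, Notch receptors and targets were higher in Lgr5+ cells for 5 of 8 tested, and 0 were higher in Reg4+ DCS cells by limma (0 at an unadjusted p under 0.05, 1 by edgeR), with the same counts of 5 and 0 adjusted over the list alone. Notch1 (chromosome 2, 26457903 to 26516663) stood at 2.97 ± 1.52 RPM in Reg4+ DCS and 91.8 ± 1.97 RPM in Lgr5+ cells (30.9-fold, 22.7 to 48.5 without 1 library, log2 fold change −4.60, SE 0.34, adjusted p = 0.000174). Notch2 (log2 fold change −2.89), Dtx4, a ubiquitin ligase of the pathway (−4.19), and Nrarp, a feedback inhibitor that Notch induces (−1.78), moved the same way. Whether the list passed depended on the setting: camera gave an adjusted p of 0.0902 (median −1.50), and 0.434 with an estimated correlation. It passed with the replicate number as a block (0.0236), under median-of-ratios scaling (0.0495), at a minimum of 20 RPM (0.0478) and by fry (0.0177), and ranged from 0.0603 to 0.740 without any 1 library. Of the members, 2 of 5 tested were called without either Lgr5+ library.

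**Figure D2:**
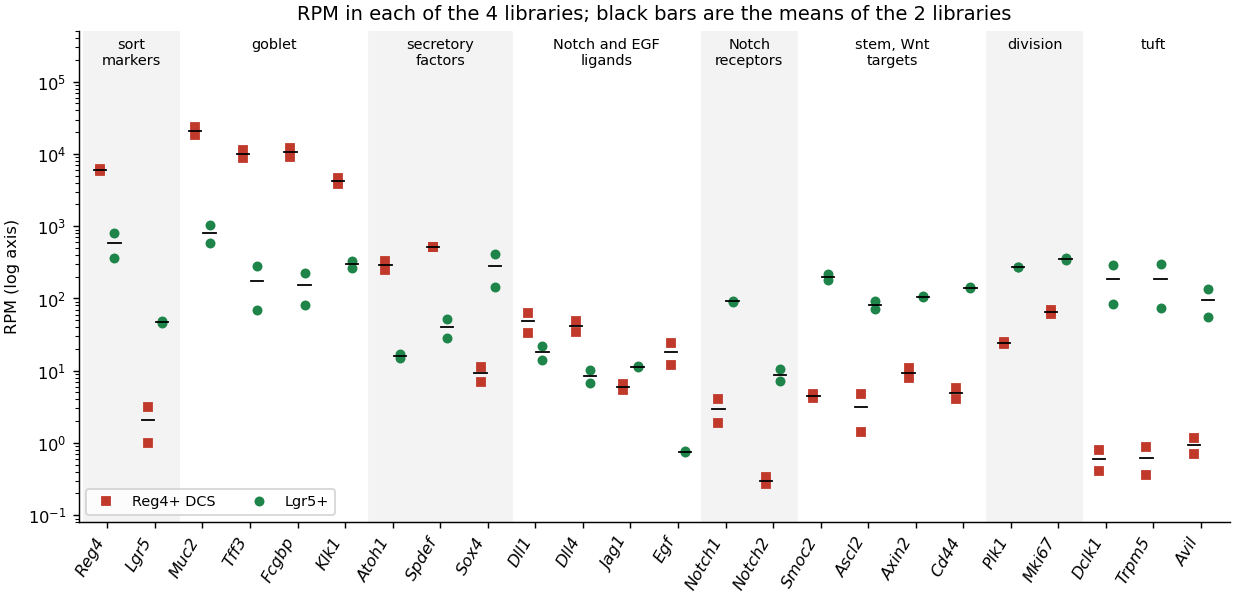
RPM of selected genes in each library on a log axis; red squares are the 2 Reg4+ DCS libraries, green circles the 2 Lgr5+ libraries, and black bars the means of each pair. The ligands Dll1, Dll4 and Egf lie higher in Reg4+ DCS libraries, while Notch1, stem cell, division and tuft cell genes lie higher in Lgr5+ libraries.

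Crypt base stem cell genes were higher in Lgr5+ cells for 20 of 23 tested, over all genes and adjusted over the list alone, and 0 were higher in Reg4+ DCS cells by limma (0 at an unadjusted p under 0.05, 1 by edgeR). Smoc2, a matricellular protein of Lgr5+ cells, stood at 4.46 ± 0.370 against 198 ± 28.0 RPM (44.5-fold, log2 fold change −5.19). Ascl2, the transcription factor that maintains intestinal stem cells, was 26.3-fold higher in Lgr5+ cells (17.05 to 57.5 without 1 library), the adhesion receptor Cd44 28.6-fold, Clca4 31.0-fold and the water channel Aqp1 14.9-fold. The symbol Clca4 had no match in GENCODE M21 and was used as listed. Prom1, a membrane glycoprotein that marks crypt cells, did not pass at 90.1 ± 24.0 against 66.7 ± 7.79 RPM (adjusted p = 0.254), and was called higher in Reg4+ DCS cells under median-of-ratios scaling (adjusted p = 0.0161) and by edgeR (0.0302). The stem cell list had a median of −2.75 (camera adjusted p = 3.55e-08, and adjusted p = 0.434 with an estimated correlation). Without either Lgr5+ library 12 of 15 tested members were called. Of the reserve stem cell list, 3 of 4 tested were higher in Lgr5+ cells (also 3 adjusted over the list alone), among them Mex3a, an RNA-binding protein of slow-cycling cells (16.6-fold), and Hopx, a homeodomain protein (3.08-fold). The third was Lrig1, an inhibitor of EGF receptors (2.43-fold, adjusted p = 0.0106), with 0.0681 without Reg4+ DCS replicate 1.

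Wnt target genes, several of them shared with the stem cell list, were higher in Lgr5+ cells for 11 of 13 tested, with 11 also adjusted over the list alone. Axin2, a feedback inhibitor that Wnt signalling induces, stood at 9.42 ± 2.20 against 106 ± 1.93 RPM (11.2-fold, log2 fold change −3.37). The Wnt target list had a median of −2.04 (camera adjusted p = 0.000121, and adjusted p = 0.434 with an estimated correlation). The members called were 7 of 9 without Lgr5+ replicate 1 and 6 of 9 without replicate 2. Ephrin receptors and ligands, which position cells along the crypt, were higher in Lgr5+ cells for 6 of 10 tested (7 adjusted over the list alone). They included Ephb3 (6.99-fold), Ephb2 (2.79-fold), Epha4 (7.84-fold) and the ligand Efna4 (16.8-fold). That list had a median of −1.11 (camera adjusted p = 0.0352, and adjusted p = 0.434 with an estimated correlation), and its adjusted p was 0.0749 without Reg4+ DCS replicate 2 and 0.258 without Lgr5+ replicate 1. Its called members were 3 of 8 without either Lgr5+ library.

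Most division genes were higher in Lgr5+ cells. All 31 tested G2/M genes and 25 of 29 S phase genes were higher in Lgr5+ cells, with 31 and 25 also adjusted over each list alone. Plk1, a mitotic kinase, stood at 24.3 ± 1.07 against 272 ± 4.65 RPM (11.2-fold), and Mki67, the proliferation marker, at 65.2 ± 6.62 against 353 ± 15.4 RPM (5.41-fold). Ube2c and Ccnb2, which drive exit from and entry to mitosis, were 5.63-fold and 5.83-fold higher, and in S phase the replication helicase subunit Mcm5 was 4.22-fold and the DNA ligase Lig1 3.77-fold higher. The medians were −2.15 for G2/M (camera adjusted p = 1.01e-13, and adjusted p = 0.177 with an estimated correlation) and −1.73 for S phase (camera adjusted p = 7.88e-07, and adjusted p = 0.434 with an estimated correlation). Under median-of-ratios scaling 30 and 21 members were called, and 30 and 17 without Reg4+ DCS replicate 1. Cell cycle inhibitors moved both ways: Btg2, an antiproliferative factor, stood at 702 ± 3.70 RPM in Reg4+ DCS and 234 ± 32.3 RPM in Lgr5+ cells (log2 fold change 1.59), while Cdkn1c, an inhibitor of cyclin-dependent kinases, was 11.2-fold higher in Lgr5+ cells (4.02 to 18.4 without 1 library; adjusted p = 0.00971; 0.0900 without Reg4+ DCS replicate 1). Of 11 tested inhibitors 1 was higher in Reg4+ DCS and 3 in Lgr5+ cells (1 and 5 adjusted over the list alone). By limma the 3 became 0 without Reg4+ DCS replicate 1 (4 at an unadjusted p under 0.05) and 1 without replicate 2, or 1 under median-of-ratios scaling, and the 1 became 2 without Lgr5+ replicate 1 and 3 under that scaling. Their list did not pass camera (adjusted p = 0.354, direction up), and its median of −0.12 became 0.34 under median-of-ratios scaling.

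Ribosome biogenesis genes, which make and process ribosomal RNA, were higher in Lgr5+ cells for 30 of 34, with 30 also adjusted over the list alone. Nop56, a core protein of box C/D snoRNPs, was 3.71-fold and Rrp9, which acts in 18S processing, 3.76-fold higher in Lgr5+ cells. Their median was −1.24 (camera adjusted p = 1.98e-06, and adjusted p = 0.434 with an estimated correlation). The count was 12 without Reg4+ DCS replicate 1 and 18 under median-of-ratios scaling. Ribosomal protein genes depended on the scaling: 27 of 78 were higher in Lgr5+ cells on the RPM scale (31 adjusted over the list alone), and 0 were called under median-of-ratios scaling with limma (2 at an unadjusted p under 0.05) and 1 by edgeR. Rpsa, which stood at 5158 ± 414 against 16069 ± 4276 RPM (adjusted p = 0.00953), and Rps26, 2.10-fold higher in Lgr5+ cells (0.0106), lost their calls under that scaling (adjusted p = 0.0941 and 0.145). Without Reg4+ DCS replicate 1 their adjusted p were 0.164 and 0.0884, and without replicate 2 they were 0.104 and 0.0649. Their list median of −0.69 became −0.18 under that scaling. Camera gave an adjusted p of 0.00237 (0.0905 under median-of-ratios scaling, 0.199 without Reg4+ DCS replicate 2, 0.0781 by fry, and adjusted p = 0.684 with an estimated correlation). The count of called ribosomal protein genes was 0 by limma without either Reg4+ DCS library (7 at an unadjusted p under 0.05 without replicate 1 and 20 without replicate 2) and 8 without Lgr5+ replicate 2, and it was 57 with the replicate number as a block. Rn45s, the ribosomal RNA precursor, also stood higher in Lgr5+ cells, at 43871 ± 4021 against 8434 ± 1060.2 RPM, and its adjusted p of 0.00241 became 0.0900 without Reg4+ DCS replicate 1 and 0.0953 without replicate 2.

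Tuft cell genes mark a rare chemosensory epithelial cell. All 21 tested members passed limma toward Lgr5+ cells, over all genes and adjusted over the list alone. Of these, 12 were listed at 0 in both Reg4+ DCS libraries, so their calls rest on that 0. The 9 above 0 in every library were higher in Lgr5+ cells, though not all were above 0 in every part of the Reg4+ DCS columns. Dclk1, a kinase that marks tuft cells, stood at 0.601 ± 0.272 RPM in Reg4+ DCS and 185 ± 144 RPM in Lgr5+ cells (log2 fold change −6.61). Trpm5, their taste-transduction channel, stood at 0.613 ± 0.364 and 189 ± 161 RPM (−6.58), and the actin-binding Avil at 0.930 ± 0.319 and 96.0 ± 57.4 RPM (−5.52). Their folds of mean RPM were 307, 308 and 103. Without 1 library these ranged from 138 to 476 for Dclk1, 122 to 532 for Trpm5 and 59.6 to 147 for Avil. Dclk1 had reads only in the second part of each Reg4+ DCS column, so its mean and fold rest in part on a listed 0. Sh2d7 and Alox5, which starts leukotriene synthesis, were listed at 0 in both Reg4+ DCS libraries, with 160.2 and 61.2 and 172 and 44.8 RPM in Lgr5+ replicates 1 and 2. The median of the 9 members above 0 in every library was −3.58 (camera adjusted p = 1.60e-05, and 0.436 with an estimated correlation, tests chosen after the values were seen). With the 12 others the median was −4.77 (camera adjusted p = 7.06e-11, and adjusted p = 0.434 with an estimated correlation). Without either Lgr5+ library only 3 members were tested, and all 3 were called.

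Other genes also had a large change toward Lgr5+ cells. Matk, a kinase that restrains Src-family kinases, stood at 0.499 ± 0.181 against 376 ± 331 RPM (log2 fold change −7.63, SE 0.59). Nrgn, a calmodulin-binding protein, stood at 0.302 ± 0.0433 against 210.2 ± 198 RPM (−6.93). In Lgr5+ replicates 1 and 2 Matk had 610 and 142 RPM, and Nrgn 350 and 70.3 RPM. Their folds of mean RPM, 753 and 696, ranged without 1 library from 284 to 1222 and from 233 to 1159. The GTPase Rac2 (−5.83), Pik3r5, a regulatory subunit of a PI3-kinase (−5.75), and the iron carrier Trf (−5.91) followed. Their limma adjusted p ran from 0.000179 for Trf to 0.000311 for Rac2. Without 1 library the folds ranged from 131 to 943 for Rac2, 169 to 825 for Pik3r5 and 65.6 to 228 for Trf. Nrgn, Rac2 and Pik3r5 had reads only in the first part of each Reg4+ DCS column. The means and folds of these 3 genes thus rest in part on a listed 0. In Lgr5+ replicates 1 and 2 Rac2 stood at 132 and 38.7 RPM and Pik3r5 at 114 and 35.7 RPM. Trf went the other way, at 83.9 and 202 RPM. Ly6g6f and Cd300lf were listed at 0 in both Reg4+ DCS libraries, with 217 and 64.5 RPM and 128 and 18.6 RPM in Lgr5+ replicates 1 and 2. Except for Trf, all these genes stood higher in Lgr5+ replicate 1 than in replicate 2, as did all 21 tested tuft genes. Whether they share a source with the tuft genes was not tested. Of the leukocyte list 1 member was tested, Ptprc, the pan-leukocyte phosphatase CD45, listed at 0 in both Reg4+ DCS libraries and at 40.1 and 9.55 RPM in the Lgr5+ libraries. Its limma call, also made adjusted over the list alone, rests on the listed 0, and without either Lgr5+ library it was not tested. The stroma and endothelium list had 9 members in the table and 0 past the filter. The erythrocyte list had 1 tested, the globin gene Beta-s, at 1.60, 12.2, 0.192 and 14.8 RPM in Reg4+ DCS replicates 1 and 2 and Lgr5+ replicates 1 and 2 (adjusted p = 0.788). Y-linked genes also moved with the populations: Ddx3y stood at 0.272 and 0.333 RPM in Reg4+ DCS and 47.1 and 58.6 RPM in Lgr5+ libraries, and Uty, Kdm5d and Eif2s3y were listed at 0 in both Reg4+ DCS libraries. Among all genes, 1638 were listed at 0 in both Reg4+ DCS libraries and above 0 in both Lgr5+ libraries, among them the glycolytic enzyme Eno1 at 0.960 and 0.629 RPM in the latter, so a 0 here says only that the gene was listed at 0.

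Enteroendocrine genes, of hormone-making cells, passed limma toward Lgr5+ cells for 3 of 9 tested (3 adjusted over the list alone). They included Ddc, which makes serotonin from its precursor (4.78-fold), and the granule protein Chga (5.58-fold, 4.18 to 8.38 without 1 library; adjusted p = 0.00670, and 0.0542 without Reg4+ DCS replicate 1). The third was St18, a zinc finger factor, listed at 0 in both Reg4+ DCS libraries, with 41.1 and 7.04 RPM in the Lgr5+ libraries, and its call rests on that 0. Their median was −0.95, or −0.86 over the 8 members above 0 in every library, and the list did not pass camera (adjusted p = 0.203). The count was 1 without Lgr5+ replicate 1 and 5 with the replicate number as a block. Absorptive colonocyte genes went both ways, with 6 of 27 higher in Reg4+ DCS cells and 10 higher in Lgr5+ cells (6 and 11 adjusted over the list alone). The sulfotransferase Sult1a1 was 7.23-fold higher in Lgr5+ cells (5.29 to 11.4 without 1 library). Ndrg1, a differentiation-associated gene, was 10.5-fold and Guca2b, the hormone uroguanylin, 6.85-fold higher in Reg4+ DCS cells. The list did not pass camera (adjusted p = 0.610), whose direction was up although the median was −0.99 and the mean −0.71. Without Lgr5+ replicate 1 it passed in the upward direction (adjusted p = 0.0420) and without Lgr5+ replicate 2 in the downward one (0.0226). Its members higher in Reg4+ DCS cells were 3 without Reg4+ DCS replicate 1, and those higher in Lgr5+ cells were 6 without either Reg4+ DCS library.

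Of 15 cytokine, chemokine and growth factor genes, 3 were higher in Reg4+ DCS and 6 in Lgr5+ cells (3 and 6 adjusted over the list alone). Ccl6, a chemokine for macrophages, stood at 1847 ± 563 against 77.4 ± 33.4 RPM (23.9-fold), and Il13ra1, a chain of the interleukin-13 receptor, was 3.95-fold higher in Reg4+ DCS cells. Il4ra, which pairs with it, was 2.38-fold higher (1.76 to 3.67 without 1 library; adjusted p = 0.0250), with 0.123 without Reg4+ DCS replicate 1, 0.0835 without replicate 2 and 0.110 without Lgr5+ replicate 2. Kitl, the ligand of the Kit receptor, was 4.91-fold higher in Lgr5+ cells. The list did not pass camera (adjusted p = 0.354, direction up, against a median of −0.25 that became 0.19 under median-of-ratios scaling; 0.0398 without Lgr5+ replicate 1). The 6 became 3 without Reg4+ DCS replicate 1 or without Lgr5+ replicate 1. Antigen presentation genes were higher in Lgr5+ cells for 7 of 13, and adjusted over the list alone 1 was higher in Reg4+ DCS and 7 in Lgr5+ cells. They included the class II chaperones Cd74 (17.2-fold, 8.59 to 25.9 without 1 library) and H2-DMa (9.29-fold, 5.63 to 17.5) and the class II chain H2-Eb1 (7.53-fold, 3.82 to 15.5; adjusted p = 0.0125, and 0.0743 without Reg4+ DCS replicate 2). Under quantile scaling the limma calls of H2-DMa (adjusted p = 0.0567) and H2-Eb1 (0.0704) were lost. The antigen presentation list had a median of −1.03 and did not pass (camera adjusted p = 0.478). Its 7 calls became 4 without Reg4+ DCS replicate 1, replicate 2 or Lgr5+ replicate 1, and 0 by limma without Lgr5+ replicate 2 (2 at an unadjusted p under 0.05), while median-of-ratios scaling gave 2 higher and 3 lower in Reg4+ DCS cells. Of 6 BMP and TGF-beta genes 1 was called, also adjusted over the list alone, the inhibitor Smad6 (2.28-fold higher in Lgr5+ cells, adjusted p = 0.0302), whose call was lost under median-of-ratios scaling (0.131) and without any 1 library (between 0.0555 without Reg4+ DCS replicate 2 and 0.173 without Lgr5+ replicate 1). That list did not pass camera (adjusted p = 0.682, direction up), and its median of −0.24 became 0.26 under that scaling.

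Immediate early and heat shock genes, which respond to cell handling, were higher in Reg4+ DCS cells for 8 of 23 and in Lgr5+ cells for 1 (10 and 1 adjusted over the list alone). Cyr61, a secreted matrix protein, was 2.80-fold higher, Dusp1, a phosphatase of MAP kinases, 2.30-fold and the AP-1 subunit Fosb 2.02-fold. Dusp1 had an adjusted p of 0.0121 (0.0727 without Reg4+ DCS replicate 2) and Fosb of 0.0153 (0.0713 without Reg4+ DCS replicate 1 and 0.0941 without replicate 2). Hspa8, a constitutive chaperone, was the member higher in Lgr5+ cells (1.95-fold, adjusted p = 0.0354), a call lost under median-of-ratios scaling (0.306), without either Reg4+ DCS library (0.275 and 0.0801 without replicates 1 and 2) and without Lgr5+ replicate 2 (0.0885). The list had a median of 0.80 (camera adjusted p = 2.97e-07, adjusted p = 0.434 with an estimated correlation, and 0.291 by fry). The count of higher members was 2 without Reg4+ DCS replicate 2, 13 without Lgr5+ replicate 1, 4 without Lgr5+ replicate 2 and 16 under median-of-ratios scaling, and 15 with the replicate number as a block. The heat shock genes Hspa1a and Hspa1b, near-identical copies whose reads can be shared, stood at 58.1 and 807 RPM and 34.9 and 358 RPM in Reg4+ DCS replicates 1 and 2. Neither passed (adjusted p = 0.833 and 0.921), though Hspa1a was called higher in Lgr5+ cells without Reg4+ DCS replicate 2 (0.0373).

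Epcam, the pan-epithelial adhesion protein, stood at 717 ± 22.5 against 1105 ± 9.63 RPM and did not pass (adjusted p = 0.0632), but was called higher in Lgr5+ cells with the replicate number as a block (0.0200) and under quantile scaling (0.0353), and had 0.879 by DESeq2. Of 12 epithelial genes, Krt7, a keratin, was 2.48-fold higher in Reg4+ DCS cells (adjusted p = 0.00834; 0.0593 without Reg4+ DCS replicate 1 and 0.0511 without replicate 2) and Cdx2, the intestinal identity factor, 3.53-fold higher in Lgr5+ cells, and these were also the 1 and 1 adjusted over the list alone. The median was −0.16, or 0.34 under median-of-ratios scaling (camera adjusted p = 0.409, direction up). Of 17 glycolysis genes 2 were higher in Reg4+ DCS and 4 in Lgr5+ cells (2 and 4 adjusted over the list alone), with the hexokinase Hk2 2.89-fold and the aldolase Aldoc 2.67-fold higher in Reg4+ DCS cells and the pyruvate kinase Pkm 2.45-fold higher in Lgr5+ cells. Without Reg4+ DCS replicate 1 these were 1 and 0 by limma (2 and 3 at an unadjusted p under 0.05), with adjusted p of 0.0816 for Hk2 and 0.0535 for Pkm, and 2 of the 4 were called under median-of-ratios scaling. The median of −0.37 became 0.14 under that scaling (camera adjusted p = 0.625, direction up). Of 87 oxidative phosphorylation genes 1 was higher in Reg4+ DCS and 10 in Lgr5+ cells (1 and 4 adjusted over the list alone). They were led by the testis-type subunit Cox6b2 at 0.128 ± 0.0537 against 18.9 ± 5.27 RPM and by Cox7a1, a heart and muscle subunit, 5.70-fold higher in Reg4+ DCS cells. The median of −0.25 became 0.26 under that scaling, where 9 were higher in Reg4+ DCS and 4 in Lgr5+ cells and the list passed upward (adjusted p = 0.0383), against a camera adjusted p of 0.572 on the RPM scale (direction up, with a negative median and mean). The 10 became 4 without either Reg4+ DCS library and 5 without Lgr5+ replicate 2. Mitochondrially encoded genes were not analysed here.

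**Figure D3:**
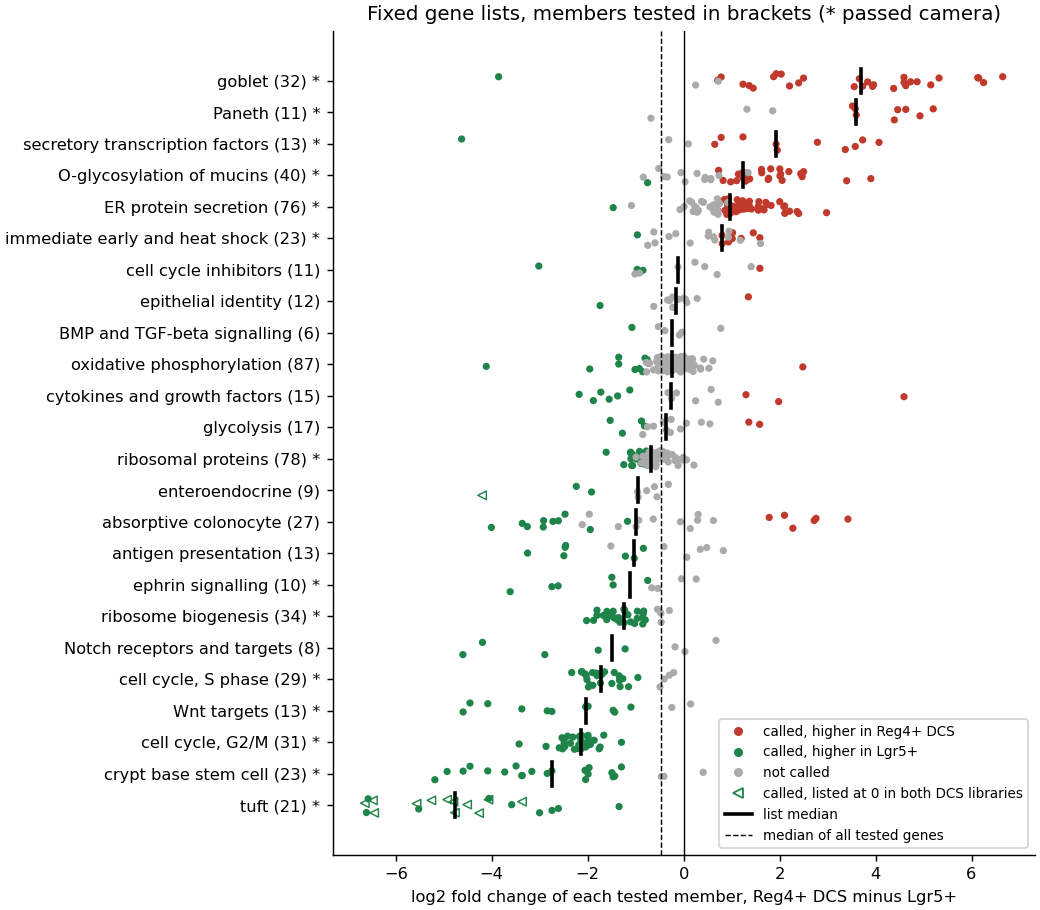
Log2 fold change, Reg4+ DCS minus Lgr5+, of each tested member of the 24 gene lists with at least 5 tested members (x axis, 1 line per list); red and green marks passed the limma test, open triangles are genes listed at 0 in both Reg4+ DCS libraries, and black bars are list medians. The 14 lists with an asterisk passed camera with its preset correlation, and 0 passed with an estimated one, which so few libraries can hardly pass. The lists run from goblet genes at the top (median 3.70) to tuft cell genes at the bottom (median −4.77, or −3.58 without those listed at 0). The dashed line is the median of all tested genes at −0.47.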

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

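The fit and list tests on genes above 0 in every library and the counts of list members and folds without each library were chosen after the result was seen; the other settings were planned. Over genes named with values and settings, 2540 results were the same, 77 lost their call, 19 gained one and 28 changed direction. The 28 were of 7 genes that did not pass, and none was called in the other direction; the cause was not tested. With median-of-ratios scaling, with or without the block, log2 fold changes were 0.19 for Areg, 0.12 for Hbegf, 0.35 for Ddx3x and 0.20 for Hspa1a, and under TMM 0.13, 0.0571, 0.28 and 0.14. Areg had 0.0946 under quantile scaling. By edgeR and DESeq2, Hbegf had 0.0509 and 0.0659, Ddx3x 0.32 and 0.33, and Hspa1a 0.89 and 0.90. Leave-one-out values ranged from −0.77 to 0.16 (Areg), −1.43 to 1.61 (Beta-s), −0.39 to 0.0694 (Ddx3x), −0.25 to 0.41 (Xist), −2.19 to 1.58 (Hspa1a) and −1.53 to 1.80 (Hspa1b). The total of 3475 changed genes stayed within 1.5 times except without Reg4+ DCS replicate 1 or Lgr5+ replicate 2; leave-one-out totals ranged from 1419 to 2637. The planned pseudocounts, filters and eBayes options gave totals of 3316 (no trend) to 3855 (no filter), except 2620 at a minimum of 20 RPM, RPM without ribosomal protein genes and the 10 highest gave 3668, and 3463 genes were called among those above 0 in every library. The split moved most with scaling. Genes higher in Reg4+ DCS cells numbered 1591 (median-of-ratios), 1360 (quantile), 1441 (TMM), 1393 (edgeR) and 1449 (DESeq2), and 349 to 706 in leave-one-out. Those higher in Lgr5+ cells numbered 1297, 1347, 1428, 1361 and 1268 in the same order, and 1060 to 2288 in leave-one-out. These scalings centre the genes by construction, and whether total RNA differed between the cell types was not measured. In leave-one-out, fewer libraries and fewer genes past the filter can lower the counts. They do not account for the gap between the fits without Reg4+ DCS replicate 1 and without replicate 2. Those fits tested 9999 and 9962 genes, with median log2 fold changes of −0.35 and −0.61. The cause of that gap was not tested.

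With the replicate number as a block, 4444 genes were called (910 and 3534 in the 2 directions), including all 3475, and with median-of-ratios scaling added 1984 and 1669. The replicate differences of the 2 populations correlated weakly across genes (Pearson 0.212, Spearman 0.171), and no source says whether a number marks a shared round, so this stays open. Of the lists, 15 passed under the block against 14 without it.

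No list passed camera with a correlation estimated from the 4 libraries (0 lists, against 14 with the preset one, 14 by fry, 14 on genes above 0 in every library, where 0 passed with an estimated correlation, and 14 or 15 under the block, median-of-ratios scaling, a pseudocount of 5 and a minimum of 20 RPM); leave-one-out gave 12 to 14. The version with an estimated correlation has few degrees of freedom, so it does not decide whether the 14 calls hold. Directions of lists that did not pass changed in some settings, and the cause was not tested. By fry, which reads the genes' own shift and not that against other genes, adjusted p was 0.478 for absorptive colonocyte and for BMP and TGF-beta genes, 0.406 for cell cycle inhibitors and for cytokines, 0.274 for epithelial identity and for glycolysis, and 0.0237 for oxidative phosphorylation, all downward. The 14 by fry were not the same lists: ribosomal proteins (0.0781) and immediate early genes (0.291) lost their call, and Notch receptors (0.0177) and oxidative phosphorylation gained one. Colonocyte genes turned downward under the block (0.605) and median-of-ratios scaling (0.550), and ranged from 0.0226 to 0.619 in leave-one-out. Antigen presentation turned upward at a minimum of 20 RPM (0.888), without Lgr5+ replicate 2 (0.649) and without Reg4+ DCS replicate 2 (0.976), with leave-one-out values from 0.270 to 0.976. Without Lgr5+ replicate 2, BMP and TGF-beta genes (0.649; leave-one-out 0.324 to 0.999) and glycolysis (0.747; leave-one-out 0.199 to 0.902) turned downward. Depth limits genes near 1 RPM, where a value rests on few reads.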

Other observations

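The genes in this and the next paragraph were chosen after their values were seen. Kcnq1, a potassium channel of the basolateral membrane that supports chloride secretion, stood at 5.39 ± 1.96 RPM in Reg4+ DCS and 301 ± 67.0 RPM in Lgr5+ cells (n = 2 each, limma log2 fold change −5.58, adjusted p = 0.000116), and its partner Kcne3 at 63.6 ± 19.2 and 427 ± 99.9 RPM (−2.74). Cftr, the apical chloride channel, was 17.3-fold higher in Lgr5+ cells (11.1 to 39.5 without 1 library). The calcium-activated potassium channel Kcnma1 and its auxiliary subunit Lrrc26 went the other way, 19.2-fold (13.8 to 31.5 without 1 library) and 21.1-fold (14.7 to 37.3) higher in Reg4+ DCS cells. Receptors higher in Reg4+ DCS cells included Ffar2, which senses short-chain fatty acids (9.85-fold), Ffar4, which senses long-chain fatty acids (9.51-fold), and the muscarinic receptor Chrm1, which acetylcholine activates (3.84-fold).

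Syt7, a calcium sensor of exocytosis, was higher in Reg4+ DCS cells, at 515 ± 2.88 against 34.7 ± 18.6 RPM (14.9-fold, 10.8 to 23.95 without 1 library), as were the granule GTPases Rab27a (5.66-fold, 3.85 to 10.6), Rab27b (3.94-fold) and Rab3d (3.35-fold). The glutathione transferases Mgst1 (21.8-fold) and Gsta3 (13.8-fold), the quinone reductase Nqo1 (17.4-fold) and the carboxylesterases Ces1d (18.5-fold) and Ces2a (10.7-fold) were higher in Lgr5+ cells. These genes do not stand for others of their kind, which were not counted. Gsta3, Ces1d and Ces2a belong to families of close paralogs whose reads can be shared. All genes of both paragraphs passed the limma test, with adjusted p up to 0.00342, for Rab27a.

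All tests of the 3 patterns that follow were chosen after the result was seen. The first pattern is that 79.0% of calls on the RPM scale were higher in Lgr5+ cells, with a median log2 fold change of −0.47 over all tested genes. Depth stays open: the median was still −0.47 with every library thinned to 3699224 reads, but thinning keeps each gene's expected share and so decides nothing. Abundant secretory transcripts under a fixed sum also stay open: genes called at least 4-fold in either direction took 32.0% and 23.3% of the RPM in Reg4+ DCS libraries and 10.3% and 8.79% in Lgr5+ libraries, and without them the median of the other 9364 genes moved from −0.44 to −0.13. As these genes were picked by their change, the move restates their shares and is no separate support, so composition cannot be told apart from a lower level of many genes in DCS cells, a biological difference.

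The second pattern is that tuft cell genes stood higher in Lgr5+ libraries, 9 of the 21 tested with values above 0 in every library and 12 listed at 0 in both Reg4+ DCS libraries. Leukocytes in the sort were argued against: Ptprc reached 40.1 RPM in Lgr5+ replicate 1, but the highest of Coro1a, Laptm5, Lsp1 and Tyrobp, abundant in leukocytes, was 2.11 RPM. Tuft cells within the Lgr5-GFP gate, which should exclude cells without the reporter, are a candidate source: all 21 were higher in Lgr5+ replicate 1 than in replicate 2, by a median of 1.56 on the log2 scale, against −0.11 for crypt base stem cell genes, a difference of 1.66, as a varying admixture would give, but colonocyte, Paneth and goblet genes also stood higher in that library (medians of 1.23, 0.98 and 0.56), so the shift was not particular to tuft genes. Expression by Lgr5+ cells themselves that varied between rounds stays open, as no single-cell data were used here. None of the tuft genes was in another of the lists, but several are also expressed by blood cells.

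The third pattern is that Y-linked genes stood at or near 0 in Reg4+ DCS libraries. All 4 of Ddx3y, Eif2s3y, Kdm5d and Uty were above 5 RPM in both Lgr5+ libraries and below 1 RPM in both Reg4+ DCS libraries, but only Ddx3y was above 0 in the latter, with Eif2s3y at 17.9 and 25.1, Kdm5d at 6.72 and 10.4 and Uty at 12.5 and 11.6 RPM in Lgr5+ replicates 1 and 2. Reads of the X-linked homolog assigned to Ddx3y were argued against, since Ddx3y was 0.212% and 0.189% of Ddx3x in Reg4+ DCS and 24.5% and 39.8% in Lgr5+ libraries, at least 115.6-fold apart. Mice of different sex behind the sorted populations stay open: Ddx3y goes with such a difference, but it is 1 gene, and a listed 0 is no measured value. Ddx3y too had reads only in the first part of each Reg4+ DCS column. Xist, which females express, stood at 121, 130.3, 150.2 and 94.7 RPM in Reg4+ DCS replicates 1 and 2 and Lgr5+ replicates 1 and 2. Both Lgr5+ libraries thus held reads of Xist and of all 4 Y-linked genes. The labels do not give the sex of the mice, so sex cannot be separated from cell type for genes that differ between sexes.

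Between the Lgr5+ libraries, colonocyte genes were higher in replicate 1 for 26 of 27 and immediate early genes for 22 of 23 (median log2 difference 0.39). Of 14314 genes decoded uniquely in both Reg4+ DCS columns, 1120 were above 0 only in the first part of both columns and 181 only in the second part of both, while 1641 were at 0 in all 4 parts and 11363 above 0 in all 4. The 1120 included Nrgn, Rac2, Pik3r5, Cox6b2, Notch2 and Ddx3y, and the 181 included Dclk1. For 4381 genes at 20 RPM or more in all parts, the SD of the log2 difference was 0.462 between the parts of replicate 1 and 0.311 between those of replicate 2, and 0.412 to 0.480 between parts of different replicates.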
